A study of Mus musculus with 2 samples.

How the data were processed

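H3K4me2, histone H3 dimethylated at lysine 4, was mapped by ChIP-seq in forebrain tissue of mouse embryos of the B6NCrl strain at embryonic day 13.5, with male and female embryos pooled. There was 1 group with 2 samples, which the labels name biological replicates 1 and 2 and trace to separate tissue samples under a shared donor entry. The labels give a fragment size range of 300 to 500 without a unit. No second tissue, age, treatment or untreated group was part of the material used here, so every comparison was made between replicates, between peak lists, between genome regions or between sets of genes.

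The authors deposited 4 peak lists in narrowPeak format on mm10. Per the deposited file listings, the list of each replicate was derived from that replicate's own filtered alignment and its own control, the pooled list from both alignments and both controls, and the replicated list from the pooled list together with both replicate lists. The peak caller, its version, its threshold, the aligner and the rule that keeps a pooled peak in the replicated list are not given in the sources used here. The deposited start and end positions were used as given, counted from 0 in the lists and from 1 in all coordinates reported. The authors' signal value of each peak is a score whose definition is not given in the sources used here, and it was used only to rank peaks within a list. The authors' −log10 p-value and −log10 q-value of each peak were used only to rank or filter peaks within a list, and every peak of every list had a −log10 p-value above 2. The scores of single peaks were not compared between lists, and where a cut-off was applied to several lists it only filtered each of them. Total read counts were not used here, so the depth of each library is unknown, and a library sequenced more deeply would be expected to yield more weak peaks. A peak missing from a list therefore means that no peak was called there, not that the mark was absent.

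Peaks were annotated with the GRCm38.p6 sequence and the GENCODE M21 genes. All peak ends lay inside the chromosome lengths of that assembly. Comparisons used chromosomes 1 to 19, X and Y, and 21853 protein-coding genes. Peaks on scaffolds outside these assembled chromosomes were left out of the comparisons. Replicates were compared by the share of peaks that overlapped a peak of the other replicate by at least 1 bp, by the Jaccard index of covered bases, and by rank deciles of −log10 p within each list. The overlap that covered length alone would give came from 100 seeded shuffles of replicate 1 within its chromosomes. Domains were made by joining replicated peaks no more than 1 kb apart. A promoter was the sequence within 1 kb of a transcription start site (TSS) of a protein-coding gene, and a gene counted as marked when a peak overlapped that window at any of its annotated TSSs. Peaks outside promoters were assigned to exons, then introns, then intergenic sequence, and were called distal. Shares of categories were set against 100 seeded shuffles. Promoters were put into CpG classes from 500 bp windows within 1 kb of the most upstream TSS. The class was high where a window had a CpG observed-to-expected ratio over 0.75 and GC content over 55%, low where no window exceeded a ratio of 0.48, and intermediate otherwise. Covered length, called breadth here, was the number of bases under peaks within 10 kb of the most upstream TSS, averaged over both replicates. That window can hold the promoter of a neighbouring gene and can miss an alternative TSS.

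The 16 gene lists covered transcription factors of the telencephalon, of the diencephalon and hypothalamus, and of the midbrain, hindbrain and spinal cord, the Hox genes, neural progenitor, neuronal, and astrocyte and oligodendrocyte genes, and developmental signalling genes. Further lists held transcription factors of non-neural lineages, terminal genes of other organs, erythroid, endothelial, microglia and macrophage, mesenchymal and meningeal, and housekeeping genes, and olfactory and vomeronasal receptor genes. The lists, the tests, the 13 motifs, the alternatives not named below as later additions and the rule for naming genes were fixed before the data were examined. Named genes were those with a TSS in the 10 broadest domains, the 3 members of each list with the greatest covered length, up to 2 members of each list with no peak within 10 kb in either replicate, the 10 genes with most distal peaks, the genes of the fixed loci (Foxg1, Dlx1-Dlx2, Dlx5-Dlx6 and the 4 Hox clusters), and the 5 list members called in only 1 replicate with the greatest difference in covered length.

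Marked shares of lists were compared with all other protein-coding genes by two-sided Fisher's exact tests. Covered lengths of the marked members of a list were compared with 100000 random lists of the same size drawn from all marked genes, using the median, by a two-sided permutation test that required at least 3 marked members. Mean numbers of distal replicated peaks per gene, each peak being given to the nearest protein-coding TSS, were compared with 100000 random lists of protein-coding genes in the same way. The smallest p-value those permutations can give is 2e-05. All p-values over lists were adjusted by the Benjamini-Hochberg method. These p-values describe sets of genes in these peak lists, and genes are not replicates of the tissue. Neighbouring genes that share peaks or windows were counted as separate genes. Motif content of distal replicated peaks was compared with flanks of the same length starting 5 kb from each edge and overlapping no pooled peak, as Mantel-Haenszel odds ratios over GC strata of 5 percentage points, with 95% intervals. Intervals of shares are 95% Wilson intervals and cover counting error only. With 2 replicates, a spread is given as a standard deviation over 2 values, which is itself imprecise. No test between the replicates was made.

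The alternatives were a −log10 q-value of at least 5, each replicate alone, promoter windows of 500 bp and 2.5 kb, only the most upstream TSS, at least 50% of the peak inside the promoter window, the pooled list, high CpG promoters only, covered length within 5 kb, random lists matched on CpG class or on the distance between neighbouring genes, distal peaks over 2.5 kb from a TSS, flanks at 20 kb, motifs without GC strata, other joining distances, other overlap rules, the top 20000 peaks and shuffles outside assembly gaps. Added after the data were seen were tests within promoters not of the high CpG class, the width of a gene's own domain, random lists matched on the signal value of the promoter peak, and rules of own making for a replicated peak. The tests were run on simulated data with 20000 genes and lists of 20, 100 times each. For list tests, each run held a single list, called at an unadjusted p-value under 0.05. These rates therefore do not describe calls adjusted over 16 lists, or lists of other sizes. With no difference simulated, 0% of lists were called for marked promoters, 2% for breadth and 7% for distal peaks. A marked share raised to 97% was called in 96% of runs and one lowered to 30% in 90%. A 2-fold difference was called in 90% of runs for breadth and 46% for distal peaks, and a 3-fold difference in 100% and 82%. The motif interval held the true odds ratio in 94% of runs. Python 3.11.15 was used with numpy 2.4.6, scipy 1.17.1, pysam 0.24.0 and matplotlib 3.10.9.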

Results

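H3K4me2 is found at the promoters of genes and at other regulatory sequence such as enhancers. It was mapped in the forebrain, the part of the embryonic brain that forms the telencephalon and the diencephalon, of B6NCrl mouse embryos at embryonic day 13.5. The 2 biological replicates gave 54497 and 53742 peaks, covering 58.9 and 55.7 Mb, with median widths of 600 and 556 bp. The pooled list held 56109 peaks over 64.5 Mb. The replicated list, which served as the main set of peaks, held 41009 peaks over 60.4 Mb (2.22% of the chromosomes) with a median width of 1007 bp. Sequencing depth was unknown, so the lists could not be compared at equal depth.

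The first comparison asked how far the replicates shared their peaks. Of the replicate 1 peaks, 77.0% (41944 of 54486) overlapped a peak of replicate 2, and 81.8% of the replicate 2 peaks overlapped a peak of replicate 1. Shuffled replicate 1 peaks overlapped in 4.00% ± 0.08 (SD over 100 shuffles). At promoters the replicates differed little, with 14493 genes marked in both, 102 in replicate 1 alone and 110 in replicate 2 alone. Of the 1756 distinct genes in the fixed lists, 14 were called in a single replicate. Hoxc4, Hoxc5, Hoxb5 and Hoxc8, homeobox genes that pattern the trunk, and the endothelial gene Mmrn2 showed the greatest differences in covered length among them. Hoxc5 had 0.608 kb covered in replicate 1 and 0 kb in replicate 2, and Mmrn2 had 0 and 0.383 kb. The strongest peaks were shared throughout, at 100% in the top 3 deciles of each list, and in the weakest decile the shares were 31.3% for replicate 1 and 39.8% for replicate 2. The replicates' peaks had 77.4% of their covered bases in common (Jaccard index). A few long peaks and many short ones weigh differently in these measures, and requiring an overlap of at least 50% of both peaks gave 62.5% for replicate 1.

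**Figure D1:**
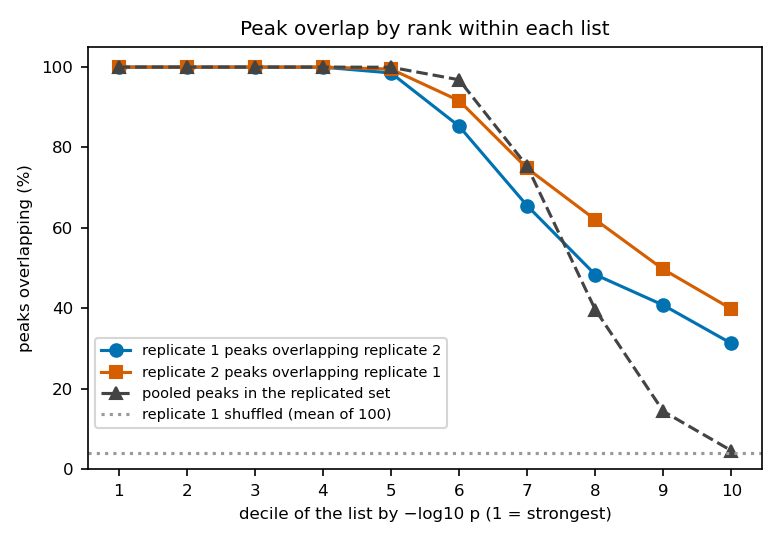
Share of peaks (%) against rank decile within each list by −log10 p, with decile 1 the strongest, where circles show replicate 1 peaks overlapping replicate 2, squares the reverse, triangles pooled peaks in the replicated set, and the dotted line the mean of 100 shuffles (4.00%). Overlap stays near 100% to decile 5 and falls to 31.3% and 39.8% in decile 10, where 4.58% of pooled peaks are in the replicated set.

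The second comparison set the replicated list against the pooled list. All 40998 replicated peaks on the main chromosomes had the coordinates of a pooled peak, and they made up 73.1% of the 56098 pooled peaks there. The share was 100% in the top 4 deciles of pooled peaks, 75.4% in decile 7, 14.4% in decile 9 and 4.58% in decile 10. A peak of both replicates overlapped 38481 pooled peaks (68.6%) by at least 1 bp. The replicated list held 2705 peaks that did not overlap both replicates and lacked 188 that did, so that rule does not rebuild it.

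Among the 10 broadest H3K4me2 domains, those with a protein-coding TSS lay over transcription factor genes of the forebrain and of neural progenitors. No test of domains for such genes was made. With peaks up to 1 kb apart joined, the widest, on chromosome 13 from 78169882 to 78212280, spanned 42.4 kb around Nr2f1, a nuclear receptor gene that patterns the cortex, and measured 42.3 ± 0.07 kb in the replicates (SD, n = 2). It was followed by the paired zinc finger genes Zic1 and Zic4 on chromosome 9 (39.7 kb), the POU factor gene Pou3f3 on chromosome 1 (36.9 kb), the homeobox genes Dlx5 and Dlx6 of the ventral telencephalon on chromosome 6 (35.9 kb), and Sox2, a progenitor factor, on chromosome 3 (34.8 kb). Foxg1, which specifies the telencephalon, shared a domain with Gm43517 on chromosome 12 (30.7 kb), and Nr2f2 on chromosome 7 had 30.6 kb. The other 3 of the 10 broadest domains held no protein-coding TSS and lay on chromosome 3 (38.0 kb), chromosome 13 (33.8 kb) and chromosome 7 (31.3 kb). Just below these ranked the domains of Lhx2 (29.0 kb), Nfib (28.2 kb), and Bcl11a with A830031A19Rik (28.1 kb), which complete the 10 broadest domains with a protein-coding TSS and were added after their widths were seen. In all, 33436 domains had a median width of 1297 bp. Over all of them, the 13769 with a protein-coding TSS had a median width of 2656 bp and the 19667 without one 759 bp. Of the 207 domains over 10 kb, 187 (90.3%) held a TSS. Widths depended on joining nearby peaks, since with only touching peaks joined the 10 domains with a protein-coding TSS were all narrower and their order changed. Lhx2 was then widest of them (26.1 kb), followed by Bcl11a (17.8 kb) and Pou3f3 (17.2 kb), and Nr2f1 was narrowest (9.11 kb). The domain at Foxg1 was 30.6 kb in replicate 1 and 16 kb in replicate 2.

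Chromosome X carried fewer peaks per Mb than the autosomes in both replicates. X had 7.64 ± 0.11 peaks per Mb and the autosomes 21.4 ± 0.22 (mean ± SD, n = 2), a ratio of 0.356 ± 0.009. Chromosome 11 was densest, with 33.6 ± 0.03 peaks per Mb and 13.4 protein-coding genes per Mb, against 5.54 genes per Mb on X. The Y chromosome held 12 and 13 peaks in the replicates. The embryos were of both sexes, so X was present in fewer copies than autosomes in the male part of the tissue and Y in all of it.

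In the replicated list, promoters held more peaks than exons, introns or intergenic sequence. Of the replicated peaks, 39.2% lay at promoters, 9.33 times the shuffled share of 4.20% ± 0.10 (SD over 100 shuffles). Exons held 12.2% (0.994 times the shuffled share), introns 26.7% (0.808 times) and intergenic sequence 21.9% (0.434 times). Promoters were assigned first, so their excess lowers the shares left for the other categories. A share below the shuffled one does not by itself show that peaks outside promoters avoid that category. For the replicated list, all but the exon share lay outside the range of the 100 shuffles. In the replicates, whose lists hold more weak peaks, 33.1% ± 0.90 lay at promoters and 32.9% ± 0.48 in introns (SD, n = 2). Replicate 1 had more peaks in introns (33.3%) than at promoters (32.5%), and replicate 2 had more at promoters (33.7%) than in introns (32.6%). Exon shares in replicates 1 and 2 lay above the range of their shuffles, at 1.12 and 1.16 times the shuffled mean. Intron shares there were 0.952 and 0.928 times it. The 16062 promoter peaks had a median width of 2191 bp and the 24936 distal peaks 667 bp. A long noncoding RNA gene had its TSS within 1 kb of 5.85% of the distal peaks.

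A majority of protein-coding genes carried H3K4me2 at a promoter, and CpG content separated marked from unmarked genes. Replicated peaks marked 66.5% (14538 of 21853; 95% Wilson interval 65.9 to 67.1%) of the genes, and the replicates marked 66.8% ± 0.03 (SD, n = 2). In the high CpG class 98.7% of 10728 genes were marked, in the intermediate class 70.6% of 4148, and in the low class 14.7% of 6977. The replicate means were 98.7% ± 0.03, 71% ± 0.17 and 15.2% ± 0.02, so differences between the classes far exceeded the spread between replicates. Requiring at least 50% of the peak inside the window marked 56.3% of genes.

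Several lists of genes of the developing forebrain were marked in full at an annotated TSS. All 25 telencephalic transcription factor genes, all 18 of the diencephalon and hypothalamus, all 20 neural progenitor genes, all 22 neuronal genes and all 22 developmental signalling genes had a marked promoter in the replicated set and in each replicate, as did all 20 housekeeping genes. Other protein-coding genes were marked in about 66.5%. Transcription factor genes of the midbrain, hindbrain and spinal cord were marked in 18 of 20, and the exceptions were Hoxb1 and Phox2b, the latter named after its value was seen. At the other end stood genes of differentiated cells from elsewhere. Among terminal genes of other organs 5 of 24 were marked, and the liver genes Alb and Afp had no peak within 10 kb. Of the erythroid genes, Klf1 and Gypa alone were marked (2 of 11), and of the microglia and macrophage genes 1 of 10, P2ry12, which was named after its value was seen. Alas2 and Epb42 of the erythroid list and Csf1r and Cx3cr1 of the microglial list had no peak within 10 kb. Olfactory and vomeronasal receptor genes, which act in sensory neurons of the nose, were marked in 4 of 1465 (0.273%, 95% Wilson interval 0.106 to 0.700%), among them Vmn1r4.

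The lists above the other genes had Benjamini-Hochberg adjusted p-values of 2.87e-04 for telencephalic factors, 0.00142 for diencephalic factors, 9.25e-04 for progenitor and housekeeping genes, 5.11e-04 for neuronal and signalling genes and 0.0443 for midbrain, hindbrain and spinal cord factors (two-sided Fisher's exact tests over 16 lists). By the same exact test, the lists below were terminal genes (adjusted p = 4.65e-05, odds ratio 0.132), erythroid genes (adjusted p = 0.00227, odds ratio 0.112), microglia and macrophage genes (adjusted p = 9.25e-04, odds ratio 0.0558) and receptor genes, whose p was too small to compute and was set to 1e-300 before adjustment (odds ratio 0.0011). The remaining lists did not pass the threshold of this test. Hox genes were marked in 21 of 39 (adjusted p = 0.157, Fisher's exact test as for all lists), astrocyte and oligodendrocyte genes in 8 of 16 (adjusted p = 0.214), factors of non-neural lineages in 12 of 24 (adjusted p = 0.157), endothelial genes in 7 of 12 (adjusted p = 0.551), and mesenchymal and meningeal genes in 8 of 10 (adjusted p = 0.546). The myelin genes Plp1 and Mobp, the thymic factor gene Foxn1 and the endothelial receptor gene Tek had no marked promoter and no peak within 10 kb. The call for midbrain, hindbrain and spinal cord factors was lost with stricter peaks and with only the most upstream TSS (85% marked in each case), while stricter peaks put Hox genes below the other genes (48.7% marked), and the most upstream TSS did so for factors of non-neural lineages (41.7%). At the most upstream TSS alone, 88.9% of diencephalic factors, 95% of progenitor and of housekeeping genes, 90.9% of neuronal genes and 95.5% of signalling genes were marked, and their calls held. The share of marked terminal genes fell to 4.17% with the 500 bp window, and with the 2.5 kb window that of microglial genes rose to 30% and that of receptor genes to 0.546%, with all of these lists still below the other genes. Promoter CpG content differed between the lists, and within the high CpG class no list stood above the other genes.

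Hox genes were the exception within the high CpG class. There 18 of 27 Hox promoters were marked against 98.8% of the other genes (odds ratio 0.025, adjusted p = 5.55e-10 by two-sided Fisher's exact test, the lowest over all alternatives for this list, which reached 0.636), with 20 marked in replicate 1 and 18 in replicate 2. Hox genes lie side by side in 4 clusters and can share a peak, which this test ignores by counting each as a separate gene. Hoxc11 of this class and Hoxb1 of the intermediate class had no peak within 10 kb, whereas Hoxd8 and Hoxd9 were marked and had 3.26 ± 0.07 and 2.78 ± 0.18 kb covered (SD, n = 2). Hoxa3 had no marked promoter but 2.78 ± 0.15 kb covered within 10 kb. Outside the high CpG class, a split added after the data were seen, 35.4% of other genes were marked, against 14 of 14 neuronal genes (adjusted p = 4e-06), 6 of 6 telencephalic factors, 6 of 6 signalling genes, 5 of 5 progenitor genes, 5 of 5 housekeeping genes and 4 of 4 diencephalic factors (adjusted p = 0.0363, with the other lists between these values, all by Fisher's exact test). In that class 3 of 1464 receptor genes were marked, and the calls for terminal, erythroid and microglial genes and for midbrain, hindbrain and spinal cord factors were lost. The split joins the intermediate class, marked in 70.6%, with the low class, marked in 14.7%. Of the 14 neuronal genes all but Dcx and Rbfox3 were intermediate, while most terminal genes were low. CpG content was therefore not held equal in these tests.

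H3K4me2 spread furthest around telencephalic transcription factor genes. Their median covered length within 10 kb of the TSS was 13.3 ± 0.12 kb (SD of the replicate medians, n = 2), against 2.94 kb in random lists of marked genes. Within the list, Nr2f1 had 19.3 ± 0.11 kb covered, Dlx6 18.2 ± 0.09 kb and Foxg1 17.7 ± 0.58 kb of the roughly 20 kb possible. Neural progenitor genes followed with a median of 8.83 ± 0.45 kb, led by Pou3f3 (19.7 ± 0.02 kb), Sox2 (19.4 ± 0.03 kb) and Pou3f2 (18.3 ± 0.37 kb). Developmental signalling genes had 5.83 kb (5.90 kb in each replicate), with the ephrin receptor gene Epha4 at 13.8 ± 0.12 kb, the hedgehog receptor gene Ptch1 at 10.2 ± 0.41 kb and Wnt7b at 9.43 ± 0.41 kb. Neuronal genes had 5.39 ± 0.43 kb, with the vesicular GABA transporter gene Slc32a1 at 14.5 ± 0.16 kb, Neurod2 at 13.7 ± 0.43 kb and Myt1l at 11.8 ± 0.06 kb.

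Housekeeping genes had a median of 4.74 ± 0.05 kb, led by Polr2a (9.22 ± 0.18 kb), Rpl13a (8.16 ± 0.75 kb) and Hmbs (6.13 ± 0.04 kb). Diencephalic and hypothalamic factors had 4.58 ± 0.04 kb, led by Lhx5 (14.8 ± 0.25 kb), Barhl2 (13.3 ± 0.51 kb) and Lhx9 (11.7 ± 0.14 kb). Below random lists lay the marked Hox genes (1.35 ± 0.02 kb), the marked terminal genes (0.701 ± 0.099 kb) and the marked receptor genes (0.946 ± 0.006 kb). Some members without a marked promoter had covered sequence nearby all the same, such as the lung gene Sftpc (4.98 ± 0.77 kb), the muscle gene Acta1 (2.94 ± 0.02 kb), the macrophage genes Cd68 (6.48 ± 0.01 kb), Tyrobp (2.63 ± 0.02 kb) and C1qa (1.92 ± 0.14 kb), the globin gene Hba-a2 (0.879 ± 0.107 kb) and the receptor genes Olfr750 (4.51 ± 0.30 kb) and Olfr148 (2.71 ± 0.19 kb). Conversely, Elf5 had a marked promoter and Pecam1 one in replicate 1 alone, with 0 kb covered around their most upstream TSS. The hormone gene Amh, marked in replicate 2 and the replicated set, had 7.45 ± 0.01 kb, and Klf1 had 5.53 ± 0.31 kb.

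The medians of telencephalic, progenitor, signalling and neuronal genes lay above, and that of Hox genes below, random lists, each with permutation p = 2e-05, the smallest that 100000 random lists can give, and adjusted p = 5.6e-05. Windows overlap between neighbouring Hox genes and within the Dlx1-Dlx2 and Dlx5-Dlx6 pairs, so these genes do not count separately in such a test. Adjusted permutation p-values were 0.00619 for diencephalic factors, 0.00268 for housekeeping genes, 0.00191 for terminal genes (5 marked) and 0.00605 for receptor genes (4 marked). The threshold was not passed by factors of the midbrain, hindbrain and spinal cord (3.22 kb, adjusted p = 0.599; Mafb 6.51 ± 0.20 kb, Egr2 4.62 ± 0.27 kb, Atoh1 4.31 ± 0.10 kb), astrocyte and oligodendrocyte genes (2.58 kb, adjusted p = 0.599 by permutation; Olig2 11 ± 0.15 kb, Pdgfra 7.0 ± 0.02 kb, Cnp 2.77 ± 0.05 kb) or factors of non-neural lineages (2.30 kb, adjusted p = 0.26; Foxa1 4.49 ± 0.02 kb, Tal1 4.00 ± 0.67 kb, Gata6 3.72 ± 0.16 kb). The same held for endothelial genes (2.17 kb, adjusted p = 0.281 by permutation; Sox18 4.67 ± 0.15 kb, Kdr 2.28 ± 0.37 kb, Egfl7 2.25 ± 0.74 kb) and mesenchymal and meningeal genes (3.26 kb, adjusted p = 0.629 by permutation; Prrx1 7.21 ± 0.03 kb, Foxc1 6.09 ± 0.21 kb, Pdgfrb 4.22 ± 0.66 kb). The erythroid list (Gypa, 1.12 ± 0.07 kb) and the microglial list had too few marked members for this test. The diencephalic call was lost with stricter peaks (median 3.66 kb), within 5 kb (2.99 kb) and for the gene's own domain (3.12 kb), and the housekeeping call within 5 kb (3.45 kb). The narrower window, which caps the length at about 10 kb, gave telencephalic factors a median of 7.15 kb. The terminal call was lost with random lists matched on CpG class, the Hox, terminal and receptor calls were lost with lists matched on signal value, and factors of non-neural lineages fell below random lists within 5 kb (1.47 kb) and for the own domain (1.07 kb).

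**Figure D2:**
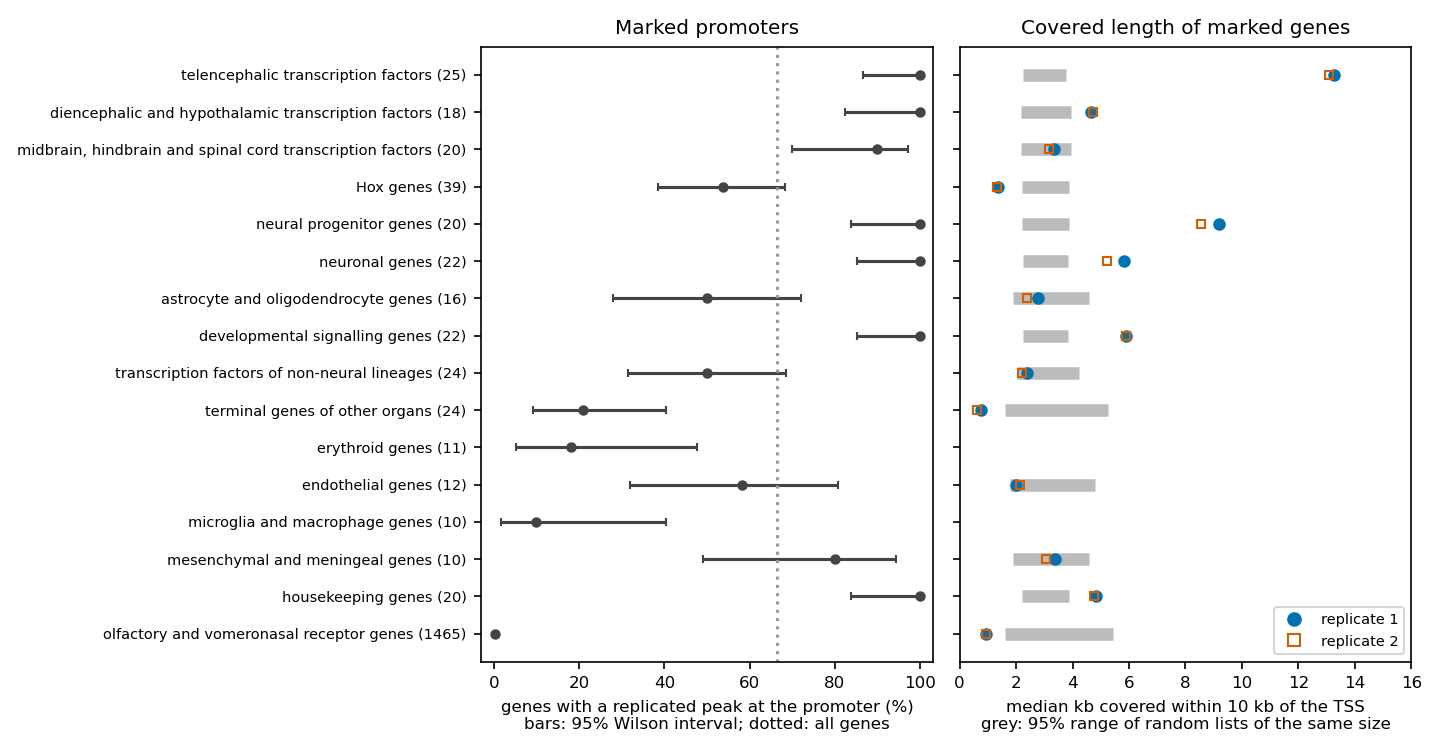
Left, percent of each list's genes with a replicated peak at the promoter, with 95% Wilson intervals and a dotted line at the share of all genes (66.5%, list sizes in parentheses); right, median kb covered within 10 kb of the TSS among marked members in replicate 1 (filled circles) and replicate 2 (open squares), with grey bars for the 95% range of random lists of the same size. Telencephalic factors stand apart at 13.3 and 13.1 kb, and lists with fewer than 3 marked genes are blank on the right.

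The fixed loci showed the same contrast along the chromosome. Peaks covered 97.1% ± 1.03 of the Dlx1-Dlx2 locus on chromosome 2 (71528113 to 71546754), 93.3% ± 0.82 of Dlx5-Dlx6 on chromosome 6 (6863334 to 6882085), and 86.2% ± 2.16 of Foxg1 with 10 kb on each side on chromosome 12 (49372660 to 49396861; SD, n = 2). Dlx1 had 14.6 ± 0.64 kb covered within 10 kb of its TSS, Dlx2 11.6 ± 0.39 kb and Dlx5 11.1 ± 0.12 kb. The Hox clusters were covered in small part: HoxA on chromosome 6 (52155590 to 52260880) 7.10% ± 0.26, HoxB on chromosome 11 (96194316 to 96368256) 2.42% ± 0.45, HoxC on chromosome 15 (102921103 to 103036852) 3.44% ± 0.66 and HoxD on chromosome 2 (74668310 to 74765142) 10.3% ± 0.18. Marked promoters numbered 6 of 11 in HoxA, 4 of 10 in HoxB, 3 of 9 in HoxC and 8 of 9 in HoxD. No test was made between loci. The difference between the Dlx loci and the Hox clusters was many times the spread between replicates, which shows how calls repeat and not how loci vary. The loci also differ in extent: the Dlx loci run from TSS to TSS over 18.6 and 18.8 kb, the Hox clusters over 96.8 to 174 kb.

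**Figure D3:**
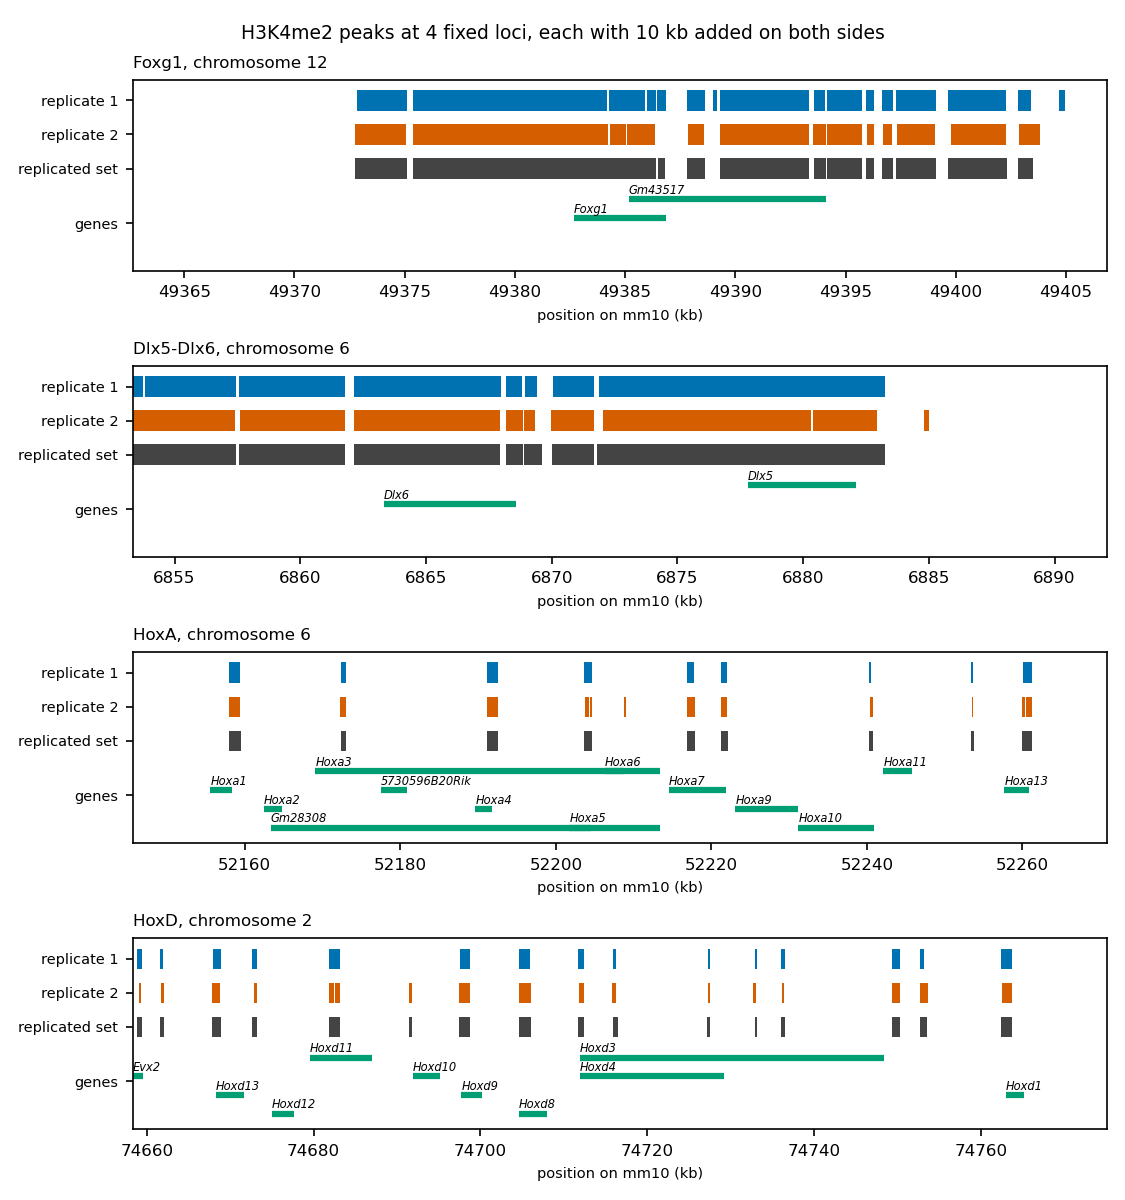
Peaks (boxes) of replicate 1, replicate 2 and the replicated set, and protein-coding genes (green bars), at Foxg1, Dlx5-Dlx6, HoxA and HoxD, each with 10 kb added on both sides, against position on mm10 in kb. At Foxg1 and Dlx5-Dlx6 the peaks are nearly continuous in both replicates, while those in HoxA and HoxD are short and separate.

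Distal H3K4me2 peaks were most numerous around neural progenitor genes and telencephalic factors. They also exceeded random lists around diencephalic factors, neuronal genes, signalling genes, and factors of the midbrain, hindbrain and spinal cord. Separate peaks of a broad domain count as distal when over 1 kb from every protein-coding TSS, as upstream of Dlx6 in its 35.9 kb domain. Distal counts and breadth are therefore not independent, and the share of such peaks was not counted. Neural progenitor genes had on average 10.8 distal replicated peaks nearest to their TSS, 9.46 times the mean of random lists, and telencephalic factors 9.04 (7.91 times). Diencephalic factors had 6.94, neuronal genes 5.82, signalling genes 5.73 and factors of the midbrain, hindbrain and spinal cord 4.85. Genes with most distal peaks were Auts2 (52), Zfp608 (49), Nfib (46), Gse1 (44), Zfhx3 (44), Adgrl2 (39), Pbx1 (38), Sox2 (38), Gm11146 (37) and Tcf4 (36). Of these, Nfib, Zfhx3, Pbx1, Sox2 and Tcf4 encode transcription factors. Hox genes (0.41) and receptor genes (0.0478) had fewer distal peaks than random lists.

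Over all protein-coding genes the mean was 1.14 distal peaks, and 8716 genes had at least 1. The replicates, each with more weak peaks, gave higher counts, such as 85 and 76 for Auts2, and means of 8.91 and 8.68 for signalling genes and 8.27 and 8.77 for neuronal genes. Adjusted permutation p-values were 8e-05 for progenitor genes, telencephalic and diencephalic factors and receptor genes (p = 2e-05, the smallest the permutations can give), 1.28e-04 for neuronal genes, 1.6e-04 for signalling genes, 9.6e-04 for midbrain, hindbrain and spinal cord factors and 0.036 for Hox genes. The remaining lists did not pass the threshold. In simulation a 2-fold difference was called in 46% of runs, for a single list of 20 genes without adjustment. The adjusted calls made here were not simulated. Astrocyte and oligodendrocyte genes had 2.38 distal peaks (2.09 times random lists, adjusted permutation p = 0.151), mesenchymal and meningeal genes 2.70 (2.36 times, 0.151), microglia and macrophage genes 1.90 (1.67 times, 0.373), endothelial genes 1.5 (1.32 times, 0.539) and factors of non-neural lineages 1.46 (1.28 times, 0.539). Housekeeping genes had 1.25 (1.1 times, adjusted permutation p = 0.729), terminal genes 0.417 (0.366 times, 0.142) and erythroid genes 0.273 (0.239 times, 0.206). Replicates 1 and 2 alone gave 2 and 1.8 for housekeeping genes, 0.542 and 0.792 for terminal genes and 0.455 each for erythroid genes, none past the threshold. Genes with wide spacing collect more distal peaks, and against random lists matched on the distance between neighbouring genes the progenitor excess was 4.80 times and the telencephalic one 3.44 times (adjusted permutation p = 1.07e-04 for both), the diencephalic one 3.09 times, the midbrain, hindbrain and spinal cord one 2.65 times, the signalling one 2.49 times and the neuronal one 2.45 times. Under that match the Hox mean was 1.24 times the random mean and not past the threshold, and with stricter peaks it stayed below the random mean (0.385 distal peaks per gene) but lost the call.

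Of the 13 motifs, 6 were more frequent in distal peaks than in flanking sequence of the same GC strata and 5 less frequent. The palindromic motif of the NFI family, factors of neural and glial development, had an odds ratio of 3.87 (95% interval 2.17 to 6.87) and was present in 0.19% of peaks. The POU motif followed at 2.07 (1.92 to 2.22), the homeodomain motif at 1.87 (1.79 to 1.95), the RFX motif at 1.39 (1.31 to 1.47), the bHLH motif CAGCTG at 1.31 (1.27 to 1.36) and the SOX motif at 1.28 (1.24 to 1.33). The less frequent motifs were AP-1 at 0.834 (0.792 to 0.879), CTCF at 0.885 (0.810 to 0.966), ETS/PU.1 at 0.891 (0.825 to 0.961), the other bHLH motif, CAGATG, at 0.893 (0.863 to 0.924), and GATA at 0.905 (0.852 to 0.961). The neuronal repressor motif NRSF/REST was at 1.04 (0.879 to 1.24), and the liver motif HNF1 occurred in 0% of peaks, so it had no odds ratio. These values came from 24194 distal peaks with at least 1 flank and 43412 flanks, and a short motif of a family does not show which factor binds. Peaks were not paired with their own flanks within the strata. Lengths can therefore differ within a stratum, and the intervals treat peaks and flanks as independent. In the single replicates the NFI odds ratio was 5.53 for replicate 1 and 7.42 for replicate 2. The CTCF interval held 1 with stricter peaks (0.84 to 1.01) and with flanks at 20 kb (0.866 to 1.03), and without GC strata the directions of CTCF (1.02) and ETS/PU.1 (1.02) turned, each with an interval that held 1. In that setting the homeodomain odds ratio was 1.17 (1.12 to 1.21) and the SOX one 1.03 (1.00 to 1.07), the CAGATG interval held 1 (0.967 to 1.03), and NRSF/REST was at 1.26 (1.08 to 1.48).

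**Figure D4:**
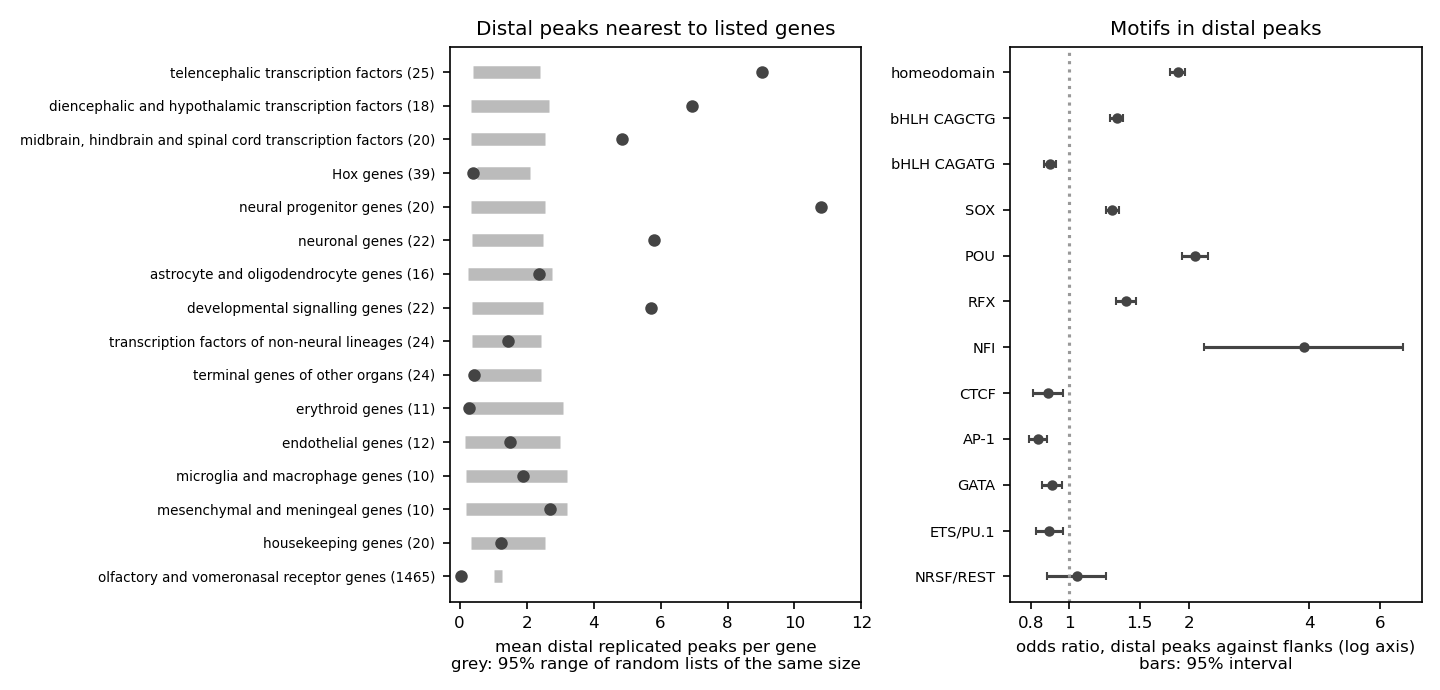
Left, mean number of distal replicated peaks per gene in each list (points) with the 95% range of random lists of the same size in grey; right, odds ratio of each motif in distal peaks against GC-stratified flanks on a log axis, with 95% intervals and a dotted line at 1. Progenitor genes (10.8) and telencephalic factors (9.04) lie farthest to the right, and NFI (3.87) has the highest odds ratio with the widest interval.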

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

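Some peaks lay on sequence that no comparison used; they were counted after the lists had been seen, and no test was run on them. The replicated list held 11 peaks on 5 scaffolds outside the assembled chromosomes, the pooled list 11, and the replicates 11 and 12. They are listed here because the count is above 3, the limit that a count of 0 allows, which shows only that the lists hold peaks there. Of the replicated peaks, 4 lay on a scaffold assigned to chromosome X, 4 on scaffolds assigned to chromosome 4 and 3 on scaffolds with no chromosome assigned.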

How the results depend on the processing

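The tests within promoters not of the high CpG class, on the own domain and with lists matched on signal value, and both rules of own making for a replicated peak, were chosen after the data were seen. Direction or side of the threshold changed in 20 of 125 marked shares of single lists, 16 of 98 breadths, 4 of 80 distal means and 6 of 60 motif odds ratios, and the rest kept both. Of 144 covered lengths of named genes, with stricter peaks or within 5 kb, 77 stayed within 1 SD and 67 fell. Neither setting can raise a covered length, and genes with 0 kb covered cannot move and count as staying. Of 50 domain widths 22 stayed, 25 fell and 3 rose. The number of domains ranged from 30896 to 40998. Telencephalic factors kept their call for breadth (adjusted permutation p from 4.67e-05 to 7e-05) and for distal peaks (6.4e-05 to 1.07e-04) under every alternative run. Leaving out a replicate gave 32.5 to 33.7% of peaks at promoters and 66.8 to 66.8% of genes marked, and changed no count of lists or motifs. Replicate overlap was 68.2% for at least 50% of the peak, 62.5% for at least 50% of both peaks, 88.2% for stricter peaks and 96.7% for the top 20000, and chance overlap outside gaps was 4.11%. The rules of own making kept 68.6 and 58.1% of pooled peaks. The X to autosome ratio was 0.433 with stricter peaks. Promoter peaks made up 37.7% with the 500 bp window, 45.5% with the 2.5 kb window and 42.2% with stricter peaks. Marked genes made up 65.9% at 500 bp, 67.7% at 2.5 kb, 66.3% with stricter peaks, 63.9% at the most upstream TSS, 56.3% with at least 50% of the peak inside the window and 67.2% with the pooled list. Wider windows raise both shares, and stricter peaks or rules lower the share of marked genes, by construction. The rise of the promoter share with stricter peaks is not set that way. Within high CpG promoters 0 lists stood above the other genes and 1, the Hox genes, below. Marked shares there were 100% for astrocyte and oligodendrocyte, endothelial and receptor genes, the last a single gene. Nearly all promoters of that class are marked, which leaves a list no room to stand above. Outside the high CpG class 7 lists differed, 1 of them below, and endothelial genes (37.5%) did not differ detectably from the 35.5% of others. That split mixes the intermediate and low classes, so it does not hold CpG content equal. With lists matched on signal value, 0 lists passed the adjusted threshold on the lower side, although the terminal (0.701 kb) and receptor (0.946 kb) medians lay below the 95% range of random lists and the Hox (1.35 kb), endothelial (2.17 kb) and astrocyte and oligodendrocyte (2.58 kb) medians below their mean. Factors of non-neural lineages (2.30 kb) lay above their random mean. The breadth of midbrain, hindbrain and spinal cord factors went from above to below the mean of random lists with stricter peaks (2.69 kb), within 5 kb (2.53 kb) and for the own domain (2.72 kb), and that of mesenchymal genes with stricter peaks (2.60 kb) and for the own domain (2.60 kb), none past the threshold. Below random lists in distal peaks stood 1 list with stricter peaks and 1 under the match on territory length. That match put the Hox mean (0.41) above and the endothelial mean (1.5) below the random mean, and a 2.5 kb limit put housekeeping genes (0.85) below it, none past the threshold. Without GC strata 2 motifs were below flanks, and CTCF (1.02) and ETS/PU.1 (1.02) lay on the other side of 1 with intervals that held 1. For each of these changes not set by construction, the cause was not tested. No paired analysis was possible because there was 1 group. No read depth was known, so its limit on weak peaks could not be measured.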

Other observations

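The tests of gene families and of microRNA and germline genes were chosen after the peaks had been seen, as were the tests on the Hox genes, on chromosome X and on own domains and signal-matched lists, and the match on CpG class, planned beforehand for breadth, was chosen as a test of telencephalic breadth after its result was seen. The lists of germline genes and of microRNA genes other than Mir9 were written before their values were seen.

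Gene families sharing a symbol stem differed in breadth. Of 240 stems with at least 8 marked members, 9 had a median covered length above random lists and 14 below it, where random lists averaged about 3 kb. The LIM homeobox genes (Lhx, 9.91 kb over 8 genes, adjusted permutation p = 9.6e-04) and the Sox genes (8.63 kb over 18 genes, adjusted permutation p = 9.6e-04) were broadest, and both families overlap the fixed lists. They were followed by Pcdh protocadherins outside the tandem clusters (7.54 kb), Arid chromatin factors (6.90 kb) and the frizzled Wnt receptors (Fzd, 6.54 kb), with adjusted permutation p-values of at most 0.00384. Cbx genes (6.38 kb), Sp factors (5.81 kb), Bcl genes (5.2 kb) and Klf factors (5.19 kb) also lay above. The clustered gamma protocadherins (Pcdhga, 1.48 kb over 11 genes, adjusted permutation p = 0.0209) lay below, as did collagens (Col, 1.89 kb), cytochrome P450 genes (Cyp, 1.75 kb), the cilia genes Cfap (1.82 kb) and Dnah (1.25 kb), and Ano genes (1.18 kb). The largest stems lay below too: Zfp (2.44 kb over 347 genes), Slc (2.58 kb over 270 genes) and Gm (2.38 kb over 209 genes). The rest below were Rsph, Il, Cxcl, Acot and Prss. Tandem members share windows, so they do not count as separate genes in such a test. The random lists were not matched on CpG class. Marked genes of the low class had a median of 1.65 kb and those of the high class 3.15 kb. Family and promoter class were therefore not separated.

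The 3 domains among the 10 broadest that lacked a protein-coding TSS each held a gene of the neural microRNA miR-9. Mir9-1 lay in the domain on chromosome 3, Mir9-2 in that on chromosome 13 and Mir9-3 in that on chromosome 7, with 20.0 ± 0.04, 15.8 ± 0.40 and 19.6 ± 0.10 kb covered within 10 kb (SD, n = 2). Long noncoding RNA genes lie there too, Gm3764, C130071C03Rik and Mir9-3hg. A hypothesis from this was that neural microRNA genes may lie in broad H3K4me2 in general. A list of 22 others, written from prior knowledge without the Mir9 genes, had a median of 4.04 kb against 0.175 kb in random microRNA genes (permutation p = 4e-05, two-sided), and 17 of them had a peak within 10 kb. Mir125b-1 (13.6 kb), Mir124a-2 (13.5 kb), Mir124a-1 (11.3 kb), Mir124a-3 (10.2 kb) and Mir219a-1 (9.88 kb) had most. Mir212 and Mir132, which lie side by side and share their peaks, had 9.74 kb each and were counted as separate genes. Mir128-1, Mir218-1, Mir218-2, Mir138-1 and Mir138-2 had 0 kb. Among 28 microRNA genes of other organs the median was 0 kb (permutation p = 1), with 0 kb at the liver gene Mir122 and the muscle gene Mir206 but 7.16 kb at Mir150 and 5.94 kb at Mir142. A peak lay within 10 kb of 10 of these 28 genes. Host genes and neighbouring promoters inside the window were not separated from the microRNA genes.

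Of 10728 high CpG promoters, 141 had no replicated peak, and 98 of these had no peak within 10 kb in either replicate. Besides 9 Hox genes they included meiosis and germline genes such as Spo11, Sycp1, Sycp2, Msh4, Hormad1, Mael and Ddx4. They also included alpha protocadherin genes such as Pcdha1 and Pcdha2, and copies of near-identical genes, where reads that match several places may be lost. A germline list written before these genes were seen was marked in 4 of 13 high CpG promoters (30.8%; Tdrkh, Ddx25, Dazl and Tdrd1, named after their values were seen), against 98.8% of other high CpG genes (Fisher's exact test, two-sided p = 6.19e-15). Outside that class 1 of its 16 genes was marked, Dnmt3l, also named after its value was seen. A candidate explanation is that germline promoters lack the mark in forebrain cells, and DNA methylation, which could keep it away, was not analysed here.

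Within the high CpG class, 18 of 27 Hox promoters were marked. The unmarked genes were Hoxa2, Hoxa3, Hoxa6, Hoxa11, Hoxb5, Hoxc8, Hoxc9, Hoxc11 and Hoxc12. Against GC content stood the other high CpG promoters of equal GC, 99.6% of 540 marked, and against repeats stood a median masked share of 9.05% in the unmarked Hox windows, next to 10.4% in the marked ones. A loss of weak peaks at the replicated rule may explain part of the gap, since the pooled list marked 21 of the 27, a count between both limits set beforehand as deciding. A biological explanation was not tested, because there was no tissue with active Hox genes to compare with.

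Chromosome X had 0.356 times the peak density of autosomes. It also had fewer high CpG genes, 1.56 per Mb against 4.25. Counted per high CpG gene, distal peaks on X were still 0.723 ± 0.034 times those of autosomes (SD, n = 2), which argues against gene content as the whole cause for distal peaks. Promoter peaks were 1.48 ± 0.02 times those of autosomes per high CpG gene (2.44 against 1.65), outside both ranges set beforehand. Counted this way they were not fewer on X, where 97.4% of high CpG promoters were marked against 98.7% on autosomes. The count includes peaks at promoters of other classes, and why it was higher on X stays open. Read depth on X, which could be lower because male cells have 1 copy, and inactivation of X in female cells were not tested.

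The breadth of H3K4me2 at telencephalic transcription factor genes was set against technical explanations. The promoters of neighbours inside the window could have added covered length. The median width of the genes' own domains was 19.8 kb, above random lists. A domain joins peaks up to 1 kb apart and can itself hold a neighbour's promoter, as at Dlx5 and Dlx6. Its width therefore cannot decide this explanation. Stronger peaks might be called wider, but random lists matched on signal value reached a median of 3.59 kb at the top of their 95% range, against 13.3 kb observed. Lists matched on CpG class reached 3.80 kb. Read depth was unknown and only a single tissue was mapped, so it stays open whether the breadth is particular to the forebrain.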
